A study of Rattus norvegicus with 16 samples.

How the data were processed

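RNA from kidneys of 8 rats was hybridised to 1-colour oligonucleotide arrays, 1 array per kidney and 16 arrays in all. Per the labels, total RNA was extracted with Tri-Reagent and cleaned on RNeasy columns, and 5 to 8 µg were used to make biotin-labelled cRNA. The left kidney of each rat was its control. The right kidney was given ACTH (adrenocorticotropic hormone) in 2 rats, DEX in 2 rats and saline in 4 rats. DEX is the label's abbreviation, which the labels do not expand. The array titles give 4 saline rats, whereas the series description gives 2 rats per treatment. The titles were followed. Dose, route, duration, sex and strain are not given in the labels, so it is not known whether the hormones also reached the left kidneys.

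The deposited values are signal intensities on a linear scale, 1 per probe set (a group of oligonucleotides for 1 or more transcripts). The software and the normalization behind the authors' values are not given in the sources used here. The values ran from 5.18 to 12664, and the medians of the 16 arrays lay between 76.0 and 82.1. On a log2 scale those medians spanned 0.093, under the limit of 0.5 that had been set for rescaling, so the arrays were not normalized again. Depth has no counterpart in array data, and the number of arrays limits the precision. No deposited column was left unused.

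Values were converted to log2(value + 16). The 59 control probe sets were removed, leaving 8740. The 40% with the lowest mean over all arrays, 3496 probe sets, were left out, and 5244 were tested. Their lowest mean signal was 60.3. The platform's annotation gave 1 gene symbol for 7006 probe sets, several for 308 and none for 1426. Of the tested probe sets, 4408 had 1 symbol, and they stood for 3193 genes. Probe sets without a single symbol were tested but given no gene name. The array annotation names no genome build, so no positions are printed.

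Each probe set was fitted with limma (version 3.58.1, in R 4.3.3), with a term for each rat, a term for the right kidney and separate terms for ACTH and DEX in the right kidney. The fit left 5 residual degrees of freedom, and the moderated variance, with an intensity trend, added a prior of 7.34. There were 6 comparisons. The first 3 were the ACTH effect over saline, the DEX effect over saline, and their difference, where an effect is the right minus left change of the hormone rats minus that of the saline rats. The other 3 were right against left kidney within the saline, ACTH and DEX rats. Tests were two-sided. P values were adjusted by Benjamini and Hochberg's method over the 5244 probe sets of each comparison, and 0.05 was the threshold. Changes are given as log2 values with the standard error (SE) of the fit. Folds are on the scale of value + 16.

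There were 27 lists of genes. The 15 gene lists were glucocorticoid receptor targets, distal nephron sodium and potassium transport, circadian clock, kidney injury and immediate early response, gluconeogenesis and amino acid catabolism, fatty acid oxidation and PPAR-alpha targets, cell cycle, interferon response and antigen presentation, inflammatory cytokines and adhesion, extracellular matrix and fibrosis, cholesterol synthesis, angiotensin and vasoactive, steroid receptors and steroid metabolism, heat shock and unfolded protein response, and oxidative phosphorylation. The 12 cell type lists were markers of proximal tubule, thick ascending limb, distal convoluted and connecting tubule, collecting duct principal cell and medulla, intercalated cell, podocyte, endothelium, smooth muscle and mesangium, leukocyte, erythrocyte, adrenal cortex, and adipose tissue. Lists were tested with limma's camera on 1 probe set per gene, with a preset correlation of 0.01 and adjustment over the 27 lists, and again with a correlation estimated for each list. Members of a list were also adjusted over the list alone.

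The comparisons, lists, filters, thresholds, the rule for named genes and the alternatives were fixed before the data were examined, apart from those said below to have been added later. For each hormone effect, the 12 largest rises and the 12 largest falls were named among genes past the threshold whose change in every hormone rat lay on the same side of all 4 saline rats, and places left over were filled in order of p value. Each gene was represented by its probe set with the highest mean. For the other comparisons the number was 5 in each direction, among genes that changed alike in every rat compared. The 2 members of a list with the smallest p were named for called lists, with any further members past the threshold adjusted over the list alone. Sgk1, Nr3c1 and Hsd11b2, fixed in advance, are given in every comparison. Of other genes fixed in advance, Tsc22d3, Fkbp5 and Per1 are not named in the array annotation, and Nr3c2 and Havcr1 were under the brightness filter. Genes named outside this rule are said to have been chosen after their values were seen.

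Pairing of the kidneys was checked by correlating each rat's left and right deviations from the mean of the same treatment and side. The correlations over the 8 rats ran from 0.62 to 0.76, with a median of 0.69, across probe sets, which are not independent replicates. With rat as a random block, the consensus correlation was 0.60. The arrays fell into 2 clusters, rats 1 to 4 and rats 5 to 8, which the labels do not name. Correlations were 0.970 to 0.994 within a cluster and 0.951 to 0.976 across. Each cluster held 1 ACTH, 1 DEX and 2 saline rats, so the rat term removes a constant difference between them. The pairing correlations and the consensus correlation include that difference, so they do not show how alike the 2 kidneys of a rat were within a cluster.

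The fit was tested on simulated data, with 200 of the 5244 probe sets changed in each of 20 simulations. Each changed probe set moved alike in both rats of a hormone, with independent noise. Recovery may be lower where the 2 rats respond unequally. In the ACTH comparison it recovered 21.0% of changes of 0.5, 95.6% of changes of 1 and 99.9% of changes of 2, all on the log2 scale, and 4.79% of its calls were false. In the DEX comparison it recovered 21.9%, 95.1% and 99.8%, and 4.88% of its calls were false. A list of 15 genes shifted by 0.5 was called in 20 of 20 simulations, and 1 of 520 unchanged lists was called. The simulated genes varied independently, whereas members of real lists can vary together. The share of false list calls in the data was therefore not tested.

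Alternatives fixed in advance covered the rat block (none, random, or right kidneys only), scaling (quantile normalization or centring on the median), pseudocounts of 1 and 64, no brightness filter or a 60% filter, a variance prior without trend or robust, array weights, 1 probe set per gene, a fit to only the rats compared, a threshold of 0.1, leaving out each rat, an estimated correlation within lists and, for the overlap of both effects, disjoint pairs of saline rats. Leaving out an ACTH or DEX rat leaves that hormone with 1 rat, which is assumed to vary like the others. Alternatives added after the data were seen were a right kidney by cluster term, a fat marker score as a covariate, and fits to rats 1 to 4 or rats 5 to 8 alone. Files were read and figures drawn with data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.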

Results

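Expression was measured in both kidneys of 8 rats. The right kidney had been given ACTH in 2 rats, DEX in 2 rats and saline in 4 rats, and the left kidney served as the control of the same animal. The comparisons ask what each hormone changed in the treated kidney relative to saline, and whether the hormones differ. Array numbers, not depth, set the precision. The arrays formed 2 clusters that the labels do not name, rats 1 to 4 and rats 5 to 8, with 1 ACTH, 1 DEX and 2 saline rats in each.

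ACTH raised Gp2, a membrane glycoprotein, 3.22-fold over saline (log2 change 1.69 ± 0.24 SE, 2 ACTH and 4 saline rats, adjusted p = 0.00958). It raised Tspo, the mitochondrial translocator protein, by 1.21 ± 0.17 (adjusted p = 0.00903) and Gstm2, a glutathione transferase, by 1.21 ± 0.18 (adjusted p = 0.00958). Prlr, the prolactin receptor, fell by 1.32 ± 0.15 (adjusted p = 0.0047), and Slco1a1, an organic anion transporter, fell by 1.26 ± 0.16 (adjusted p = 0.00583). The abundant kidney androgen-regulated protein Kap fell by 0.78 ± 0.12 (adjusted p = 0.018). Its mean signal was 2223 in the 2 ACTH right kidneys (SD 539), against 4117 in the 4 saline right kidneys (SD 1206) and 4189 in the 8 left kidneys (SD 871).

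Tspo signal averaged 1216 in the ACTH right kidneys (SD 235, n = 2), 471 in the saline right kidneys (SD 73.5, n = 4) and 478 in the left kidneys (SD 71.8, n = 8). Prlr signal averaged 103 (SD 34.3), 255 (SD 18.0) and 274 (SD 50.4) in the same order. The right minus left change of Gp2 was 1.16 and 2.34 in the ACTH rats, against a mean of 0.06 ± 0.05 (SD, n = 4) in the saline rats. For Prlr it was −1.33 and −1.39, against −0.04 ± 0.12 (SD, n = 4). All 3 other Prlr probe sets had negative values.

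The other named rises were Ndrg2, a stress- and steroid-regulated gene, at 1.13 ± 0.20; Dnase1, the secreted nuclease, at 0.94 ± 0.17; Bhmt, which remethylates homocysteine, at 0.93 ± 0.16; the glycolytic enzyme Pkm at 0.87 ± 0.16; and the potassium channel Kcnq1 at 0.73 ± 0.14. Gnmt, a glycine methyltransferase, rose by 1.09 ± 0.20 (adjusted p = 0.04) in 1 of its 3 probe sets, chosen after its values were seen, while the others gave 0.74 and 0.71 and did not pass. Falls were seen for Hnmt, which methylates histamine, at −1.26 ± 0.23, the collagen gene Col3a1 at −1.07 ± 0.20 (second probe set −0.33 ± 0.31, not past the threshold), the guanylate cyclase subunit Gucy1b2 at −0.94 ± 0.18 and the galactosyltransferase B4galt6 at −0.85 ± 0.16. Several genes lay just beyond the threshold. Sult1a1, a sulfotransferase, had 1.55 ± 0.31 (adjusted p = 0.0552), and the galectins Lgals3 and Lgals1 had 0.94 and 0.88. The phosphofructokinase subunit Pfkl had 0.84. The male-typical cytochrome Cyp2c11 had −1.47, the chemokine Ccl5 was 2.00-fold lower, the prolyl hydroxylase subunit P4ha1 had −0.89, the methionine adenosyltransferase Mat2a −0.84 and the clock gene Per2 −0.73. Among the genes fixed in advance, Sgk1, a kinase induced by corticosteroids, had 0.27 ± 0.28, the glucocorticoid receptor Nr3c1 −0.09 ± 0.14 and Hsd11b2, which inactivates glucocorticoids, 0.38 ± 0.22, none past the threshold.

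In all, 26 probe sets passed in limma, 14 higher and 12 lower, against 495 at an unadjusted p under 0.05 where 262 were due by chance. They included 16 genes with a symbol, 9 higher and 7 lower. All 26, which were selected by this same contrast, had the same sign in rats 1 to 4 and in rats 5 to 8. Among the 6 probe sets without a single symbol, D31662exon#4_s_at fell by 1.70 and AF007758_g_at by 1.19, while L14003UTR#1_f_at rose by 1.31. Leaving out each rat from 1 to 8 in turn gave counts of 46, 11, 12, 9, 114, 12, 13 and 14. Gp2, Tspo, Gstm2, Prlr and Slco1a1 passed without any 1 rat, with Gp2 at 1.09 without rat 5, and each of the other named genes missed the threshold without at least 1 rat. Without the rat term the count was 0, with right kidneys alone it was 0, and after quantile normalization it was 12, of which 5 were higher and 7 lower. With the fat marker score as a covariate it was 7, and Gucy1b2, Col3a1, Ndrg2 and Bhmt had −0.51, −0.61, 0.68 and 0.59.

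**Figure D1:**
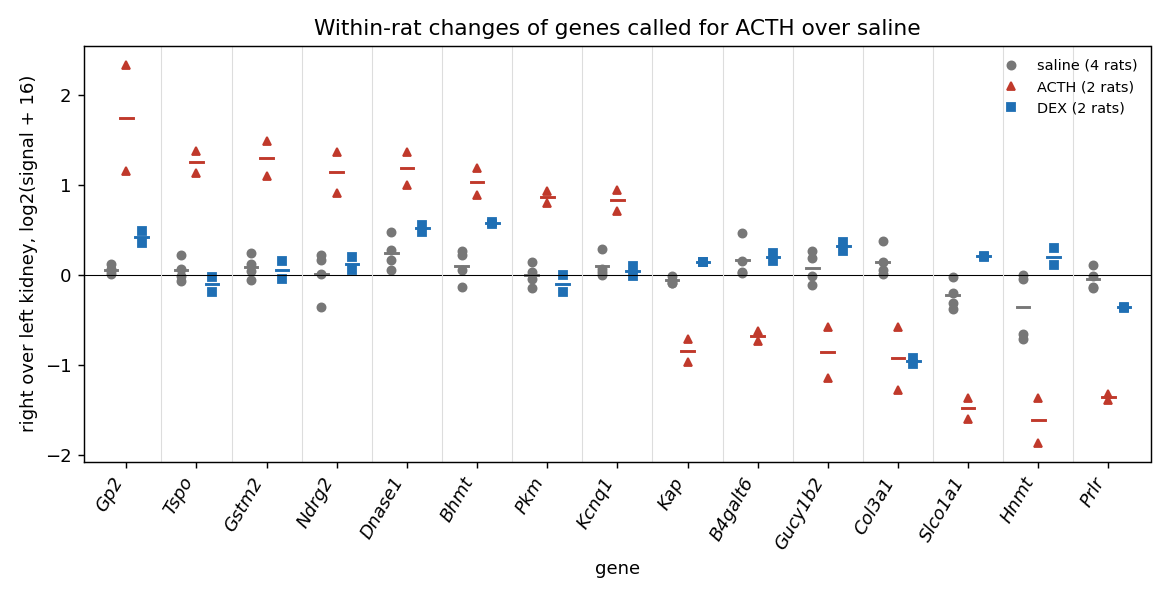
Right minus left change (log2) of the named genes in each of the 8 rats, with a point per rat and a bar for the mean of each treatment. For Prlr the ACTH rats sat at −1.33 and −1.39, against a saline mean of −0.04.

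Gene groups moved under ACTH as follows, with 8 of the 27 lists called at the preset correlation. The smooth muscle and mesangium markers rose (median 0.33, 6 of 7 positive, adjusted p = 0.000499, and adjusted p = 0.327 with an estimated correlation), with Tagln at 0.61 and Acta2 at 0.49 past the threshold adjusted over the list alone. Fat markers were higher in all 6 members (median 1.01, adjusted p = 0.00013, estimated-correlation adjusted p = 0.378), and 5 passed adjusted over the list alone, among them the desaturase Scd at 3.14 ± 0.91 and the fatty acid binding protein Fabp4, 3.02-fold higher. Their median was 1.64 within rats 1 to 4 and 0.38 within rats 5 to 8. The right kidney of ACTH rat 1 had a fat marker score of 10.0, against 7.76 in that of ACTH rat 5 and 7.13 to 7.58 in the saline right kidneys. The kidney injury and immediate early list rose (median 0.15, 16 of 21 positive, adjusted p = 0.00414, estimated-correlation adjusted p = 0.378). Lgals3, the filament protein Vim at 1.00 ± 0.30 and the heat shock protein Hspa1a at 0.53 passed adjusted over the list alone. Vim changed by 1.66 in ACTH rat 1 and 0.22 in ACTH rat 5, and its effect was 0.28 without rat 1. Distal nephron transport rose (median 0.23, 11 of 15 positive, adjusted p = 0.00702, estimated-correlation adjusted p = 0.378). There Ndrg2 passed, and the kallikrein Klk1 had 0.40. The mean of the distal transport list changed by 0.45 in ACTH rat 5 and by 0.08 in ACTH rat 1. In rat 5 the collecting duct markers changed by 0.61, the distal convoluted tubule markers by 0.44 and the erythrocyte genes by 0.88, against −0.23, 0.16 and −0.33 in rat 1. Gluconeogenesis and amino acid catabolism rose (median 0.08, 12 of 17 positive, adjusted p = 0.023, estimated-correlation adjusted p = 0.385), with Bhmt and the alanine transaminase Gpt at 0.69 ± 0.19 past the threshold adjusted over the list alone.

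Matrix genes fell after ACTH (median −0.30, 12 of 14 negative, adjusted p = 0.0167, estimated-correlation adjusted p = 0.378), and only Col3a1 passed adjusted over the list alone. The circadian clock list fell (median −0.22, 7 of 8 negative, adjusted p = 0.0167, estimated-correlation adjusted p = 0.378). In it Per2 passed adjusted over the list alone and Nr1d2 had −0.64. Interferon response and antigen presentation fell (median −0.14, 15 of 17 negative, adjusted p = 0.0216, estimated-correlation adjusted p = 0.469), with the class II genes Cd74 at −0.62 and RT1-Ba at −0.48 and 0 members past the threshold. The other Cd74 probe sets had −0.70, −0.29 and −0.18, none past the threshold. Medians in rats 1 to 4 and rats 5 to 8 were −0.52 and −0.11 for matrix, −0.33 and −0.20 for the clock, −0.34 and −0.01 for interferon, −0.01 and 0.42 for injury, 0.02 and 0.49 for distal transport, and 0.29 and 0.47 for smooth muscle. Without rat 1 the fat, clock, interferon, matrix and gluconeogenesis calls were lost. Without rat 5 the injury and distal transport calls were lost, and without rat 6 the distal transport, matrix and gluconeogenesis calls. Of these 8 calls, only injury and smooth muscle were left with the fat marker score as a covariate.

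The other lists were not called for ACTH. Medians were 0.21 for glucocorticoid receptor targets (adjusted p = 0.0735), −0.20 for thick ascending limb (0.0672), 0.22 for collecting duct (0.0657) and 0.40 for distal convoluted and connecting tubule (0.0842). Klk1 and Calb1, a calcium-binding protein, passed adjusted over the last list alone, as did Egf at −0.73 in the thick ascending limb and the angiotensin receptor Agtr1a at −0.59 in the angiotensin and vasoactive list. Medians were 0.06 for fatty acid oxidation, −0.23 for cell cycle, −0.02 for inflammatory cytokines, 0.18 for cholesterol synthesis, −0.03 for angiotensin and vasoactive, −0.08 for heat shock, 0.09 for oxidative phosphorylation and −0.14 for proximal tubule. For steroid receptors and metabolism the median was 0.00, with 5 of 10 members positive. The remaining cell type medians were 0.08 for intercalated cell, −0.01 for podocyte, −0.12 for endothelium, −0.16 for leukocyte, 0.16 for erythrocyte and 0.10 for adrenal cortex.

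No gene passed the test over all genes for DEX. Among the genes named by the rule, Col3a1 had −1.10 ± 0.20 (2 DEX and 4 saline rats, changes of −0.92 and −0.99 in the DEX rats, adjusted p = 0.729), its second probe set −0.39 ± 0.31, and Col1a1 had −0.90 ± 0.25. Sgk1 had 0.87 ± 0.28 (adjusted p = 0.999), with changes of 1.42 and 0.12 in the DEX rats. The clock output gene Dbp had 0.91 ± 0.28 and the core clock gene Bmal1 −0.75 ± 0.21. Brown fat's uncoupling protein Ucp1 had −2.24 ± 0.52, the adipocyte protease Cfd −1.48 ± 0.43 and Fabp4 −1.45 ± 0.52.

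Other genes named for DEX were the carbonic anhydrase Car4 at 1.07 ± 0.27, the phosphatase subunits Ppp1cb at 0.98 ± 0.24 and Ppp1cc at 0.78 ± 0.19, Acsm3 at 0.93 (−0.53 with right kidneys only), Afm at 0.57, Ccdc117 at 0.56, Srsf11 at 0.55, Gclm, which limits glutathione synthesis, and Bhmt both at 0.47, and Sdc4 at 0.43. On the lower side were Sncg at −0.62, Ces1e at −0.57, Nnat at −0.55, Wrap53 at −0.46, Gng11 at −0.41 and Cybrd1 at −0.39. The second Car4 probe set had 0.28 ± 0.20. Nr3c1 had −0.12 and Hsd11b2 −0.08. In limma 0 probe sets passed, and 154 had an unadjusted p under 0.05, 94 higher and 60 lower, where 262 were due by chance. Leaving out rat 3 gave 3, and leaving out rat 6 gave 2.

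**Figure D2:**
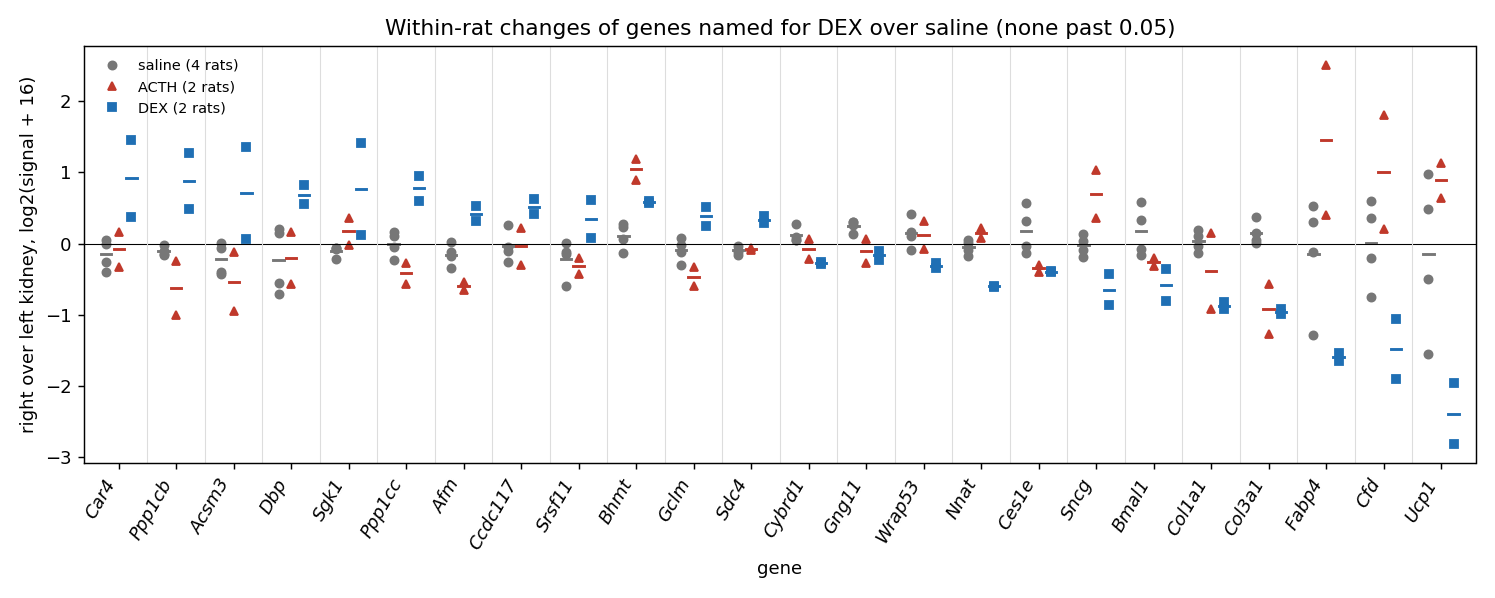
Right minus left change (log2) of the genes named for DEX in each of the 8 rats, with a point per rat and a bar for the mean of each treatment. For Col3a1 the DEX rats sat at −0.92 and −0.99, and no gene plotted passed the test over all genes for DEX.

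As groups, 8 of the 27 lists were called for DEX. Matrix genes fell (median −0.36, 13 of 14 negative, adjusted p = 2.43e-10, and adjusted p = 0.175 with an estimated correlation), and Col3a1 and Col1a1 passed adjusted over the list alone. In the left kidneys the matrix score of rats 1, 3 and 7 was highest, at 8.16, 8.14 and 8.17, against 7.86 to 8.02 in the other left kidneys. The right kidneys of DEX rats 3 and 7 had 7.80 and 7.85, against 7.97 to 8.09 in the saline right kidneys. Glucocorticoid receptor targets rose (median 0.32, 12 of 14 positive, adjusted p = 0.000379, estimated-correlation adjusted p = 0.217), with Sgk1 at 0.87 and Per2 at 0.43, neither past the threshold adjusted over the list alone. The mean of the list changed by 0.18 and 0.15 in the DEX rats, and by −0.21, 0.23, −0.37 and −0.15 in saline rats 2, 4, 6 and 8. Right over left in the DEX rats this list was not called (median 0.14, adjusted p = 0.0815). Heat shock and unfolded protein response genes rose (median 0.28, 11 of 13 positive, adjusted p = 0.000226, estimated-correlation adjusted p = 0.304). Among them were the chaperones Hspa5 at 0.67 and Dnajb9 at 0.34, neither past the threshold. Hspa5 changed by 0.69 and 0.10 in DEX rats 3 and 7 and by −1.07 in saline rat 8, and its effect was 0.37 without rat 3 and 0.40 without rat 8. A second Hspa5 probe set had 0.81 ± 0.22, not past the threshold over all probe sets. It changed by 1.05 and 0.39 in the DEX rats and by −0.39 to 0.34 in the saline rats. The mean of the heat shock list changed by 0.32 and 0.07 in the DEX rats, and by −0.01, 0.03, 0.06 and −0.29 in saline rats 2, 4, 6 and 8. Fat markers fell (median −0.81, 5 of 6 negative, adjusted p = 0.000379, estimated-correlation adjusted p = 0.304), and Cfd and Fabp4 passed adjusted over the list alone. The fat marker score was 8.00 and 8.19 in the left kidneys of the DEX rats and 7.03 and 7.13 in the right.

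Gluconeogenesis and amino acid catabolism rose with DEX (median 0.12, 11 of 17 positive, adjusted p = 0.0119, estimated-correlation adjusted p = 0.304), with Bhmt at 0.47 and Got1 at 0.37. The thick ascending limb markers rose (median 0.20, 6 of 7 positive, adjusted p = 0.0325, estimated-correlation adjusted p = 0.304), with the potassium channel Kcnj1 at 0.35 and Egf at 0.37. Endothelial markers fell (median −0.16, 5 of 5 negative, adjusted p = 0.0161, estimated-correlation adjusted p = 0.304). Both erythrocyte genes were lower (median −0.60, adjusted p = 0.0121, estimated-correlation adjusted p = 0.304), with Hbb at −0.70 and Alas2 at −0.51. The clock list was not called (median 0.13, adjusted p = 0.233), yet Dbp and Per2 were higher and Bmal1 lower adjusted over the list alone. Uncalled medians were 0.12 for distal transport, −0.10 for injury, 0.12 for fatty acid oxidation, −0.11 for cell cycle, 0.06 for interferon, −0.08 for inflammatory cytokines, 0.14 for cholesterol synthesis, −0.07 for angiotensin and vasoactive, −0.07 for steroid receptors and 0.02 for oxidative phosphorylation. Among cell types they were 0.09 for proximal tubule, −0.03 for distal convoluted tubule, −0.08 for collecting duct, 0.12 for intercalated cell, 0.05 for podocyte with a negative mean of −0.05, −0.06 for smooth muscle, −0.16 for leukocyte and 0.04 for adrenal cortex with a negative mean of −0.02.

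Within rats 1 to 4 and rats 5 to 8 the DEX medians were −0.37 and −0.26 for matrix, 0.09 and 0.23 for glucocorticoid receptor targets, 0.32 and 0.22 for heat shock, and −0.82 and −0.69 for fat. Leaving out rat 3 ended the heat shock, gluconeogenesis, endothelium and thick ascending limb calls, and leaving out rat 7 ended all of these but heat shock and also the erythrocyte call. The erythrocyte call was also lost without rat 4, the gluconeogenesis call without rat 6, the thick ascending limb call without rat 6 or 8, and the endothelium call without rat 8. The fat, thick ascending limb, endothelium and erythrocyte calls were also lost with the fat marker score as a covariate.

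**Figure D3:**
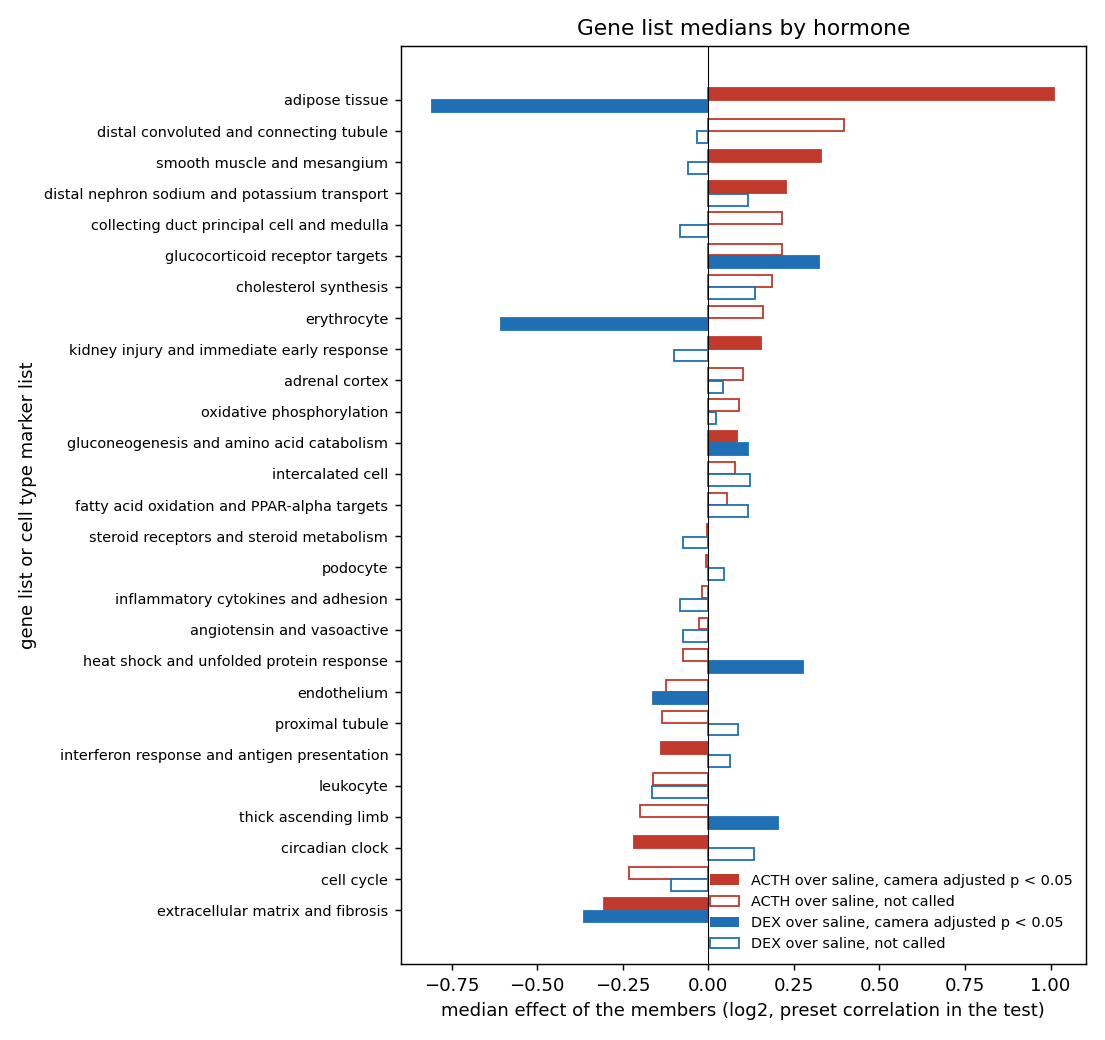
Median log2 effect of each list over saline for ACTH and for DEX, in 2 ACTH, 2 DEX and 4 saline rats, with filled bars for lists called at the preset correlation. Matrix genes had medians of −0.30 and −0.36, and fat markers 1.01 and −0.81.

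Relative to DEX, ACTH gave higher Ucp1 (3.27 ± 0.60, 2 rats each, adjusted p = 0.0351), Fabp4 (3.05 ± 0.60, adjusted p = 0.0476), Cfd (2.48 ± 0.49, adjusted p = 0.0489), Tspo (1.36 ± 0.19, adjusted p = 0.0138) and synuclein gamma, Sncg (1.34 ± 0.24, adjusted p = 0.0331). In the right kidneys Ucp1 signal was 1119 and 106 in ACTH rats 1 and 5, 53.0 and 98.2 in DEX rats 3 and 7, and up to 142 in the saline rats. In the left kidneys of rats 1, 5, 3 and 7 it was 501, 62.7, 253 and 788, so much of the difference lay there and in rat 1. Fabp4 changed by 2.51 and 0.40 in ACTH rats 1 and 5, and its difference was 2.00 without rat 1. ACTH gave lower Cyp2c11 (−1.84 ± 0.35, adjusted p = 0.0408), Hnmt (−1.82 ± 0.27, adjusted p = 0.0162), Slco1a1 (−1.69 ± 0.18, adjusted p = 0.00338), Ppp1cb (−1.51 ± 0.28, adjusted p = 0.0351) and Ppp1cc (−1.19 ± 0.21, adjusted p = 0.0331). Of these 10 genes, only Slco1a1 passed without any 1 rat. The 2 other Cyp2c11 probe sets had −1.08 and −0.03 and the other Ppp1cb probe set −0.88, none past the threshold. The largest difference, 4.80 ± 0.87 (adjusted p = 0.0345), was in the probe set K01934mRNA#2_at, which has no single symbol and was chosen after its values were seen. Sgk1 had −0.60 ± 0.32, Nr3c1 0.02 and Hsd11b2 0.46 ± 0.25, none past the threshold. In limma 30 probe sets passed, 15 higher and 15 lower, with 23 named genes, and 639 had an unadjusted p under 0.05. The split was 10 higher and 8 lower without saline rat 2, and 1 higher and 6 lower without saline rat 4. Leaving out each rat from 1 to 8 gave 100, 18, 4, 7, 88, 25, 2 and 22. The count was 0 without the rat term and 9 with a random block. With the fat marker score as a covariate it was 26, of which 2 were higher and 24 lower.

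By list, 9 differed between the hormones at the preset correlation. Higher with ACTH were fat markers (median 2.08, adjusted p = 9.68e-07, estimated-correlation adjusted p = 0.298), smooth muscle (0.45, adjusted p = 0.000416, estimated-correlation adjusted p = 0.298), injury and immediate early response (0.31, adjusted p = 0.00535, estimated-correlation adjusted p = 0.594) and collecting duct (0.29, adjusted p = 0.0483, estimated-correlation adjusted p = 0.595). Lower with ACTH were thick ascending limb (−0.41, adjusted p = 0.0118, estimated-correlation adjusted p = 0.298), heat shock (−0.34, adjusted p = 0.0296, estimated-correlation adjusted p = 0.595), clock (−0.30, adjusted p = 0.0251, estimated-correlation adjusted p = 0.298), proximal tubule (−0.26, adjusted p = 0.0347, estimated-correlation adjusted p = 0.619) and interferon response (−0.21, adjusted p = 0.0251, estimated-correlation adjusted p = 0.595). In the clock list Per2 and Nr1d2 both had −1.16. The collecting duct median was −0.06 within rats 1 to 4 and 0.64 within rats 5 to 8. The fat and smooth muscle calls held without any 1 rat. Leaving out rat 1 ended the clock, interferon, proximal tubule and thick ascending limb calls, rat 3 the interferon, heat shock, proximal tubule and collecting duct calls, rat 5 the injury, heat shock and collecting duct calls, rat 6 the collecting duct call, and rat 7 the clock, proximal tubule, thick ascending limb and collecting duct calls. With the fat marker score as a covariate only the injury call was left. The remaining 18 lists were not called.

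Across the 5244 probe sets, which are not independent replicates, the ACTH and DEX effects had a Pearson correlation of −0.05 and a Spearman correlation of −0.01. Both effects subtract the same saline rats, and simulations with no true effect gave 0.33 ± 0.02 (SD, 100 simulations) for Pearson. The simulated probe sets varied independently, whereas real ones can vary together. That SD is therefore no measure of the spread to be met in these data. With disjoint pairs of saline rats, the mean over 6 splits was −0.23 (range −0.32 to −0.14). The splits reuse the same rats, so their range is not an independent spread.

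**Figure D4:**
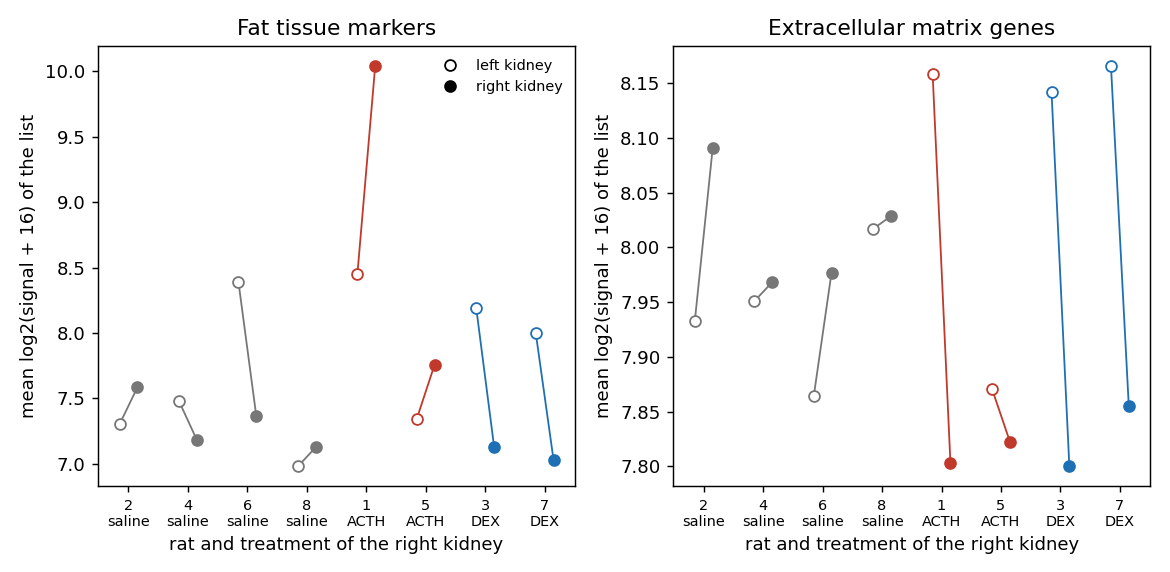
Fat marker score and matrix score (mean log2 signal of each list) in the left and right kidney of each of the 8 rats, with a line joining the kidneys of 1 rat. ACTH rat 1 had the highest fat score in its right kidney, 10.0.

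In the saline rats no gene passed the test of right against left kidney. The desaturase Scd2 had 1.00 ± 0.17 (4 rats, adjusted p = 0.144), the peroxisomal enzymes Acaa1b and Ehhadh 0.56 ± 0.12 and 0.53 ± 0.13, P4ha1 0.43 and Azgp1 0.36. Lower values were found for the probe set annotated as Crp (−0.78 ± 0.23), Cyp2c11 (−0.65 ± 0.17), the splicing factor Srsf5 (−0.50), Ptgs2, the inducible cyclooxygenase (−0.32), and Pdyn (−0.28). Sgk1 had −0.10, Nr3c1 0.14 and Hsd11b2 0.12. In limma 0 probe sets passed, and 196 had an unadjusted p under 0.05, 131 higher and 65 lower. Glucocorticoid receptor targets fell as a list (median −0.13, 11 of 14 negative, adjusted p = 0.00842, estimated-correlation adjusted p = 0.652), with Nfkbia at −0.31, a call lost without rat 2 or rat 6 and with the fat marker score as a covariate. The other 26 lists were not called.

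Within the ACTH rats, the treated kidney had lower Cyp2c11 (−2.13 ± 0.25, 2 rats, adjusted p = 0.000595), Hnmt (−1.61 ± 0.19), Slco1a1 (−1.48 ± 0.13) and Prlr (−1.36 ± 0.12) than the left kidney. The probe set M13101cds_f_at, which the array annotation names Crp, had −1.28 ± 0.32. Unnamed probe sets M13100cds#2_s_at and M13100cds#6_f_at had −1.21 and −1.18. Whether the probe set named Crp measures that gene alone was not tested. The treated kidney had higher Fasn, the fatty acid synthase (1.96 ± 0.48, adjusted p = 0.0457), Gp2 (1.75 ± 0.20), Scd2 (1.61 ± 0.24), Grifin (2.83-fold) and Sult1a1 (1.38 ± 0.25). Sgk1 had 0.17, Nr3c1 0.04 and Hsd11b2 0.51 ± 0.18, none past the threshold. In rats 1 and 5, Fasn changed by 3.38 and 0.54, Grifin by 2.40 and 0.60, Sult1a1 by 1.95 and 0.82, Gp2 by 1.16 and 2.34, Crp by −0.48 and −2.08, and the fat marker score by 1.59 and 0.41. Of the other Cyp2c11 probe sets, 1 passed at −1.33 and 1 did not, at −0.36. In limma 187 probe sets passed, 106 higher and 81 lower. Centring each array on its median gave 110 and 49, the fat marker score as a covariate gave 40 and 123, leaving out 1 rat gave 119 to 272, and a fit to the ACTH rats alone gave 0.

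Of the lists, 8 were called in the ACTH rats. The clock list had 8 of 8 members lower (median −0.23, adjusted p = 0.0078, estimated-correlation adjusted p = 0.361). Smooth muscle rose (0.33, adjusted p = 0.0077, estimated-correlation adjusted p = 0.361), as did fat markers (0.93, adjusted p = 0.0042), distal transport (0.23, adjusted p = 0.0079), injury (0.17, adjusted p = 0.0136) and gluconeogenesis (0.15, adjusted p = 0.0194). Interferon response (−0.21, adjusted p = 0.0042) and inflammatory cytokines (−0.15, adjusted p = 0.0355) fell. These last 6 lists shared an estimated-correlation adjusted p of 0.379. Without rat 1 the clock, gluconeogenesis, interferon, inflammatory and fat calls were lost, and without rat 5 the distal transport and injury calls. With the fat marker score as a covariate only the injury call was left.

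In the DEX rats, the treated kidney had values of −0.96 ± 0.17 for Col3a1, −0.87 ± 0.20 for Col1a1, −2.39 ± 0.43 for Ucp1, −0.66 ± 0.15 for the chemokine Ccl2 and −0.60 ± 0.11 for Nnat. On the higher side, Scd2 had 1.06 ± 0.24, Ppp1cb 0.88 ± 0.20, Ehhadh 0.78 ± 0.18, Ppp1cc 0.77 ± 0.15 and Bhmt 0.58 ± 0.13. Sgk1 had 0.77 ± 0.23, Nr3c1 0.02 and Hsd11b2 0.04, the last turning to −0.05 after quantile normalization. None passed in limma, where the smallest adjusted p was 0.145, and 310 probe sets had an unadjusted p under 0.05, 185 higher and 125 lower. A fit to the DEX rats alone, with 1 residual degree of freedom, gave 133. Of the lists, 13 were called, led by the fall of the matrix list (median −0.27, 13 of 14 negative) and of fat markers (−1.15, 5 of 6 negative), and the rise of gluconeogenesis (0.13, 15 of 17 positive) and proximal tubule (0.17, 12 of 15 positive). Their estimated-correlation adjusted p was 0.274 for these 4 lists. Heat shock (0.24), thick ascending limb (0.24), fatty acid oxidation (0.16) and distal transport (0.13) were also higher. Erythrocyte (−0.49), leukocyte (−0.17), inflammatory cytokines (−0.16), cell cycle (−0.15) and smooth muscle (−0.10) were lower, with estimated-correlation adjusted p values from 0.274 to 0.414. The matrix, fat and gluconeogenesis calls held without any 1 rat. Without rat 3 the distal transport, fatty acid oxidation, inflammatory, heat shock and proximal tubule calls were lost, without rat 7 the thick ascending limb and erythrocyte calls, without either the cell cycle and leukocyte calls, and without rat 1, 3 or 7 the smooth muscle call. Of the 13 calls, matrix, gluconeogenesis, inflammatory and cell cycle were left with the fat marker score as a covariate.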

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

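The tests of carried-over fat, proximal tubule content and stromal content were chosen after the results were seen. The test of androgen-responsive genes and the counts over other splits of the rats were chosen before their results were seen. The bootstrap intervals below resample genes or probe sets, not rats, so they carry no variation between rats.

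Differences between the ACTH and DEX effects were picked out because the difference itself passed limma's test, as it did for 30 probe sets. The largest, 4.80 (adjusted p = 0.0345), was in K01934mRNA#2_at, a probe set without a single symbol. Among named genes the largest were Ucp1 at 3.27, Fabp4 at 3.05 and Cfd at 2.48 (log2, adjusted p 0.0351, 0.0476 and 0.0489). Tspo at 1.36 (0.0138) and Sncg at 1.34 (0.0331) were also higher with ACTH. Lower with ACTH were Cyp2c11 at −1.84 (0.0408), Hnmt at −1.82 (0.0162), Slco1a1 at −1.69 (0.00338), Ppp1cb at −1.51 (0.0351) and Ppp1cc at −1.19 (0.0331). Other probe sets of Cyp2c11 (−1.08 and −0.03) and Ppp1cb (−0.88) did not pass. Each named gene had the same sign in rats 1 to 4 and in rats 5 to 8, which selection by this same contrast favours.

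List medians differed between the hormones for fat markers (2.08, adjusted p = 9.68e-07), smooth muscle and mesangium (0.45, adjusted p = 0.000416), injury and immediate early response (0.31, adjusted p = 0.00535) and collecting duct (0.29, adjusted p = 0.0483). They were negative for thick ascending limb (−0.41, adjusted p = 0.0118), heat shock (−0.34, adjusted p = 0.0296), circadian clock (−0.30, adjusted p = 0.0251), proximal tubule (−0.26, adjusted p = 0.0347) and interferon response (−0.21, adjusted p = 0.0251). With an estimated correlation no list differed.

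A single sample lay far from the others of its group in 4 of 114 groups examined, where chance would give about 6. These were Bhmt in the left kidney of rat 4 (7.98 log2), B4galt6 in the left kidney of rat 1 (7.22), Sncg in the left kidney of rat 7 (8.46) and the Sgk1 change of saline rat 8 (−0.21).

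The fat markers that separate ACTH from DEX also varied widely in the left kidneys, where Ucp1 signal ran from 62.7 to 788. Over the 8 left kidneys, Ucp1 and Fabp4, the only pair of genes tested, had a Pearson r of 0.975 (exact permutation p = 0.00057) and a Spearman rho of 0.857 (exact permutation p = 0.0107), with r = 0.977 without the 2 samples farthest from the median of Ucp1, r = 0.967 within rats 1 to 4 and r = 0.992 within rats 5 to 8. These genes were picked by a contrast that contains 4 of these left kidneys, so the p values are no independent support, and among the 4 saline left kidneys, outside that contrast, only rat 6 stood apart (Ucp1 signal 255, Fabp4 157, against at most 69.6 and 67.8 in the others). Fat tissue carried over at dissection in varying amounts is a candidate explanation that stays open, as do lower fat markers in the treated kidney with DEX and, since the route is not known, a hormone effect in the left kidneys of the DEX rats (scores 8.00 and 8.19). The DEX right kidneys lay 0.23 below the saline right kidneys (−0.23), at 7.03 and 7.13, and the saline range reached down to 7.13.

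With the fat marker score as a covariate, the effects of the 26 called probe sets kept their sign. Their median ratio to the values without the score was 0.94 (95% bootstrap interval 0.838 to 1.10). The median SE grew from 0.18 to 0.23, and 4 of the 26 still passed. The 26 were selected by a contrast that favours like changes in both ACTH rats, whose fat scores changed by 1.59 and 0.41. That selection favours a ratio near 1, so the ratio does not decide on carried-over fat, which stays open. The ratios ran from 0.539 to 1.34. The effects that shrank most were those of Gucy1b2 (−0.94 ± 0.18 before, −0.51 ± 0.21 after), Col3a1 (−1.07 ± 0.20, −0.61 ± 0.24), Ndrg2 (1.13 ± 0.20, 0.68 ± 0.23), Bhmt (0.93 ± 0.16, 0.59 ± 0.20), L14004UTR#1_s_at (1.19 ± 0.23, 0.75 ± 0.29) and 1 Prlr probe set (−1.33 ± 0.19, −0.85 ± 0.21). Less proximal tubule in the ACTH right kidneys is argued against as the full cause of the called falls. Its 15 markers had a median of −0.14 (95% bootstrap interval −0.28 to 0.04) against −1.21 for those falls, and 0 of them reached the smallest fall. The falls were selected as large by this same contrast, and a smaller contribution stays open. Right over left in the ACTH rats, the marker Slc34a1 had −0.94 ± 0.14 (limma adjusted p = 0.0038). Parts of the proximal tubule were not tested apart. The proximal tubule list was lower with ACTH than with DEX (−0.26, camera adjusted p = 0.0347 at the preset correlation). Lower expression of androgen-responsive genes, a hypothesis raised by Kap, Prlr and Slco1a1, cannot be told apart from other causes, since only 4 of its 10 further genes were measured, with a median of −0.23 (range −0.32 to 0.05), and Slc22a2 and Slc22a6 also stood in the proximal tubule list. Of the 15 splits of the 6 ACTH and saline rats, 1, the real one, gave as many as 26 calls and the highest of the others gave 4, but 15 splits are too few for a share under 0.05.

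Matrix genes had negative medians with both hormones. With the fat score as a covariate the median was −0.45 for DEX (95% bootstrap interval −0.696 to −0.187). For ACTH it was −0.12 (−0.468 to 0.218). The fat score changed by 1.59 and 0.41 in ACTH rats 1 and 5, whose matrix scores changed by −0.36 and −0.05. In DEX rats 3 and 7 the fat score changed by −1.06 and −0.97, so the correction for DEX rested on the other rats. The matrix scores of those DEX rats changed by −0.34 and −0.31. These opposite fat changes argue against carried-over fat acting in 1 direction as the shared cause of both falls. Saline rat 6 had −1.02 for fat and 0.11 for matrix. For each hormone taken alone, carried-over fat stays open. The left kidneys of rats 1, 3 and 7 had fat scores of 8.45, 8.19 and 8.00. That of rat 6 had 8.39, with a matrix score of 7.86. Less of all stromal and vessel cells is argued against for ACTH, where the smooth muscle markers without Acta2 had a median of 0.33 (0.116 to 0.492). The mean of the whole smooth muscle list changed by 0.21 and 0.40 in the ACTH rats, and by −0.09 to 0.001 in the saline rats. Only smooth muscle and mesangium markers entered that test, so less of other stromal or vessel cells stays open. For DEX less of all stromal and vessel cells stays open, as the markers without Acta2 had a median of −0.11 (−0.232 to 0.0517). A hormone effect on matrix genes was tested only by the comparisons themselves, and it remains a hypothesis because the left kidneys of rats 1, 3 and 7 had the highest matrix scores of the left kidneys, so part of the change lay there.

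For the saline rats, 8 of the 8 splits that part every pair gave as many calls as the real split, all 0. Without the rat term, 35 of the 35 splits of the 8 arrays did, again with 0 for the real split. With 0 real calls both counts were fixed in advance and decide nothing. The highest of the 35, 2243, came from the split of rats 2 and 4 against rats 6 and 8, which points to a structure of the arrays that the rat term removes.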

How the results depend on the processing

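The fits with a cluster term, with the fat score as a covariate, and to rats 1 to 4 or rats 5 to 8 alone were chosen after the results were seen. The 15 named ACTH genes that passed kept their sign under every alternative in which they were measured. The number past 0.05 ran from 0 (no rat block, right kidneys only, or rats 5 to 8 alone) to 15. The cause of a change was not tested unless one is given here. Dim probe sets limit what can be seen, and those tested had a mean signal of at least 60.3.

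Without a rat block, ACTH over saline had 0 calls (26 with it), ACTH over DEX 0 (30) and ACTH right over left 4 (187). The arrays' clusters then enter the residual. With right kidneys only, these were 0, 0 and 51. The overlap of the hormone effects was then 0.0262 (−0.05), Sgk1 −0.27 for ACTH over saline, 0.20 in the saline and −0.0685 in the ACTH rats, Acsm3 −0.53 for DEX, Nr3c1 0.0139 for DEX, −0.17 for ACTH over DEX and −0.0324 in the ACTH rats, and Hsd11b2 −0.0535 and the smooth muscle median −0.0221 in the DEX rats. A random block gave 9 for ACTH over DEX.

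For ACTH over saline, quantile normalization gave 12 calls, all among the 26, centring on the median 16, a robust prior 44, array weights 9, only the rats compared 13, and a threshold of 0.1 gave 54. Array weights gave 17 for ACTH over DEX, 2 for saline right over left and 65 for ACTH right over left. The fit to only the rats compared gave 0 in the ACTH and 133 in the DEX rats, with 1 residual degree of freedom. A threshold of 0.1 gave 64 for ACTH over DEX and 364 for ACTH right over left. Saline right over left, 0 as reported, had 1 call with quantile normalization, pseudocount 1, no filter, the 60% filter, no trend, the robust prior and the threshold of 0.1. Quantile normalization also turned Hsd11b2 in the DEX rats to −0.0535, the 1 reversal among 352 values under the scalings. With no filter 14 lists were called for DEX (8). With an estimated correlation 0 lists were called for ACTH and 0 for DEX. Disjoint saline pairs gave an overlap of −0.23.

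The cluster term gave 74 for ACTH over DEX, Sgk1 0.028 in the saline rats, and Nr3c1 −0.00919 and Hsd11b2 −0.0428 in the DEX rats. With the fat covariate there were 7 calls for ACTH over saline and 4 for saline right over left, ACTH over DEX had 2 higher and 24 lower (15 and 15 as reported) and ACTH right over left 40 and 123 (106 and 81), the overlap was −0.51, and 2 lists were called for ACTH (injury and smooth muscle) and 5 for DEX. Fabp4 became −0.27 for ACTH and −0.0292 for ACTH over DEX. Fat markers became −0.145, −0.0168, −0.038 and 0.0475 for ACTH, ACTH over DEX, and the ACTH and DEX rats, as they define the covariate. Nr3c1 was −0.0432 and Hsd11b2 −0.18 in the DEX rats.

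Rats 1 to 4 alone, with 1 residual degree of freedom, gave 296 calls for ACTH over saline, 40 for DEX over saline, 255 for ACTH over DEX, and 72, 443 and 178 for right over left in saline, ACTH and DEX rats. Hsd11b2 was −0.0226 for ACTH and −0.00882 for ACTH over DEX, Nr3c1 −0.0481 for ACTH over DEX, −0.079 in the ACTH and −0.0309 in the DEX rats, and Sgk1 −0.0161 in the ACTH rats. Rats 5 to 8 alone gave 0 for ACTH over saline, 0 for ACTH over DEX and 0 for ACTH right over left, with Nr3c1 0.0568 for ACTH, Sgk1 0.24 for ACTH over DEX and Hsd11b2 −0.0267 in the DEX rats.

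Leaving out 1 rat, which leaves fewer samples, gave 9 (without rat 4) to 114 (without rat 5) calls for ACTH over saline, 0 to 3 for DEX over saline, 2 (without rat 7) to 100 (without rat 1) for ACTH over DEX, 0 to 1, 119 to 272 and 0 to 4 for right over left in saline, ACTH and DEX rats, and 4 to 11 and 4 to 9 lists for ACTH and DEX. The overlap ran from −0.14 to 0.0721. Ranges that crossed 0 were Nr3c1 −0.22 to 0.0305 and Hsd11b2 −0.0224 to 0.79 for ACTH, Sgk1 −1.24 to 0.0519, Nr3c1 −0.10 to 0.15 and collecting duct −0.0627 to 0.69 for ACTH over DEX, Sgk1 −0.0161 to 0.36 and Nr3c1 −0.079 to 0.17 in the ACTH rats, and Hsd11b2 −0.0267 to 0.11 and Nr3c1 −0.0309 to 0.0743 in the DEX rats. The lone hormone rat is then assumed to vary like the others.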

Other observations

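The genes in this part were chosen after their values were seen. Scd2, a desaturase of fatty acid synthesis, was higher in the right kidney whatever the treatment. Its mean change over 5 probe sets was positive in 8 of 8 rats, from 0.47 to 1.12, with a mean of 0.80 (SD 0.26, n = 8), and 39 of the 40 single values were positive. Hmox1, the inducible heme oxygenase, had an ACTH effect of −2.12 ± 0.73 (adjusted p = 0.331) that rested on rat 1, with a change of −3.55 there and 0.20 in rat 5. A second Hmox1 probe set gave −3.28 and 0.14.

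Of 11 glutathione transferases measured, 6 had positive ACTH effects. Gstm2, at 1.21, passed the threshold, whereas Gstm1 at 0.75 (adjusted p = 0.203) and Gsta3 at −0.56 (adjusted p = 0.236) did not. Scd, the desaturase abundant in fat, changed by 2.42 and 1.75 in the ACTH rats and by −3.48 and −0.56 in the DEX rats, while the saline rats ran from −3.30 to 0.38. Among the left kidneys the fat marker score ran from 6.98 to 8.45.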
